A study of Caenorhabditis elegans with 4 samples.

How the data were processed

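Chromatin immunoprecipitation with an anti-GFP antibody was applied to whole Caenorhabditis elegans larvae that carried a GFP fusion of NHR-6, the only NR4A nuclear receptor of the worm. Per the labels' protocols, synchronised larvae were grown on 20 plates of about 4000 animals, collected 34 to 37 hours after plating for the L3 sample and 37 to 42 hours for the L4 sample, and staged by microscopy of at least 20 animals. Each precipitation used 2.2 mg of lysate protein, DNA fragments of 100 to 300 bp were cut from a gel, and libraries were sequenced on a SOLiD 5500xl instrument. The 4 libraries were 1 ChIP and 1 input library per stage. The L3 animals carried the integrated transgene sgIs1 and the L4 animals sgIs2, so that stage, strain and library coincided throughout. Control precipitations with normal rabbit IgG that the protocol mentions were not analysed here.

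The authors deposited 3 peak tables, named for L3, for L4 and for both stages, in the column layout of a MACS peak table per the file headers. For each peak the authors gave a count of tags, a score equal to 10 times the negative log10 of the peak's p-value, and a fold enrichment over the control, per the file headers. Each peak was assigned to a gene and an annotation class, and ChIPseeker is the tool named in the submitters' processing notes. The aligner, the version of the peak caller and the genome build are not given in the sources used here. The deposited tables held 21711, 18043 and 87268 lines, because a peak was repeated for each neighbouring transcript. After 1 line was kept per peak they held 5071 peaks for L3, 4547 peaks for L4 and 22127 entries for both stages. Library totals are not given in the sources used here, so the depth of each library is unknown. The tags within peaks summed to 101851 in the L3 table, 104248 in the L4 table and 1118673 over the 21368 distinct called peaks of the table for both stages.

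What each table held was tested on the files. No interval of any table overlapped an interval of another, and the intervals of the table for both stages were never narrower than the called peak beside them and were wider in 17482 entries. The L3 and L4 tables were therefore read as peaks called at that stage alone, and the third table, called the shared table here, as unions of overlapping L3 and L4 peaks. The planned design had assumed a full peak list per stage, so each stage's set was rebuilt as its own table plus the shared regions. Overlapping shared intervals (at least 1 bp) were joined into 20940 regions. The values in the shared table were read as those of the L3 ChIP. Many fold values were multiples of a step that differed between libraries. Of the folds above 5, 43.7% in the L3 table lay within 0.006 of a multiple of 0.723 and 44.2% in the L4 table of a multiple of 0.749. Of the shared folds above 5, 23.9% lay as close to a multiple of the L3 step and 1.27% to a multiple of the L4 step, against a median of 1.36% over all steps tried. Strength was therefore compared between the L3 and shared tables, and L4 values are given beside them without a comparison. The highest fold was 68 steps in the shared table, where 7 peaks stood exactly at 49.13, so shared folds near 49 are at a ceiling and can understate enrichment. The highest fold of the L4 table was 67 steps, reached only by peaks of the gene jun-1, so a ceiling in L4 was not shown on other peaks.

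Gene names came from a RefSeq gene table of assembly WBcel235, matched by locus tag for 10809 and by symbol for 681 of the 11930 gene identifiers in the files, and otherwise from the files. Among 921 short genes of equal length in both sources, 2 lay at the same position and the median shift was 39 bp, so the files use another assembly. Coordinates are printed only as the files give them, 1-based, with the build not given in the sources used here.

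Shares carry exact Clopper-Pearson 95% confidence intervals, which cover counting error only. Expected overlap came from 100 random placements of all L4 regions within their chromosomes, whose lengths were taken as the highest position in the files. Gene lists were compared with 10000 random lists of protein-coding genes matched in 10 bins on territory length, the gene plus the intergenic sequence on both sides. A list was said to lie above the random lists at a percentile of at least 97.5, and below them at 2.5 or less. With 1 ChIP per stage no test across replicates was possible and no p-value is given. On simulated data with 20000 independent genes, 2% of 200 unchanged lists passed 97.5 with matching and 5.5% without it. The simulated chance of a region was set by the same bins that were matched, and all simulated lists had the same size. This check therefore cannot show a length bias within bins, an effect of neighbouring genes or the rate for lists of other sizes. Lists with a large planted excess were recovered in 100% of cases, and recovery of smaller excesses was not simulated. A planted fold step of 0.72 was found at 0.72.

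The gene lists, the main settings and the rule for named genes were fixed before the data were examined. The rule took the genes of the 10 best-scoring peaks per table, up to 4 members of each list in order of their best shared score, and nhr-6 with a set of common transgene markers. Because the shared table held L3 values alone, the planned rank sum over both stages became the shared rank. The results of 1 gene list and 1 named gene are not reported here. The search for the NR4A response element in peaks was not run, as no genome sequence was used here. Alternatives covered the better-scoring 50% of each table, other promoter distances, removal of the widest 1% of peaks, unmatched random lists and other measures of strength. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.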

Results

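Binding of GFP-tagged NHR-6 was profiled in whole larvae at 2 stages of spermatheca development, the late L3 (34 to 37 hours after plating) and the L4 (37 to 42 hours). The spermatheca is the contractile tube of the hermaphrodite gonad in which oocytes are fertilised. Each stage had 1 ChIP library and 1 input library and no replicate, so no difference between the stages has a replicate check, and L3 and L4 animals came from different transgenic strains. Across both stages 30558 regions were listed, of which 20940 were shared, 5071 were listed for L3 alone and 4547 for L4 alone. Scores, folds and tag counts are the authors' values, and for shared regions they describe the L3 ChIP.

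The first comparison asked where NHR-6 ChIP regions lay relative to genes. Most lay within 3 kb of a transcription start site (TSS), on either side of it. A position within 1 kb of a TSS was annotated for 34.6% of the shared entries (95% CI 34.0 to 35.2), 37.3% of the peaks of L3 alone (36.0 to 38.7) and 34.6% of the peaks of L4 alone (33.2 to 36.0). Within 3 kb of a TSS the shares were 70.9%, 73.3% and 72.0%. Introns held 13.2% of shared entries, 12.4% of L3 peaks and 13.3% of L4 peaks, and exons held 3.29%, 2.17% and 2.73%. Each peak had 1 class, and peaks within 3 kb of a TSS on either side were classed as promoter. The intron and exon shares therefore leave out peaks inside genes near a TSS and are not the full share within genes. The share within 1 kb of a TSS changed little with peak strength, from 36.0% (34.4 to 37.6) of L3 peaks with scores of 50 to 60 to 33.1% (31.6 to 34.6) of those scoring 300 or more. Regions were sparser on the X chromosome than on the autosomes. There were 147.7 shared regions per Mb on X and 222.0 per Mb on the autosomes, a ratio of 0.665, and the ratios were 0.707 for L3 alone and 0.608 for L4 alone. By shared regions, chromosome I had the highest density, at 276.2 per Mb, followed by chromosome III at 274.2. Among peaks of L3 alone chromosome III was the densest, at 65.2 per Mb against 60.0 on chromosome I. No peak was listed on the mitochondrial chromosome. The placement of random genomic positions was not computed, so these shares have no background value.

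The second comparison asked how many regions L3 and L4 had in common. The 20940 shared regions were 80.5% of the 26011 L3 regions and 82.2% of the 25487 L4 regions. Random placement of the L4 regions met an L3 region 2302 times on average (range 2158 to 2400 over 100 placements), so the observed number was 9.10 times higher. Positions were drawn uniformly along each chromosome, so this ratio does not separate NHR-6 binding from other features that both libraries share. Whether an L3 peak was also listed for L4 followed its score. Of L3 peaks with scores of 50 to 60, 45.6% (43.9 to 47.3) were shared, and the share was 76.5% (75.004 to 77.9) at scores of 80 to 100 and 98.7% (98.2 to 99.1) at 150 to 200. All 3772 L3 peaks with scores of 300 or more were shared. The median score was 134.4 for shared peaks and 65.6 for peaks of L3 alone, a ratio of 2.05. The median fold was 13.5 against 9.39 and the median tag count 34 against 18. None of 10000 random draws of as many L3 peaks had a median score below 106.1. Peaks of L4 alone had a median score of 64.9, a median fold of 8.99 and a median of 18 tags in their own library. Peaks of L3 alone were also short, with 55.2% under 100 bp, compared with 34.6% of peaks of L4 alone and 28.2% of shared called peaks.

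**Figure D1:**
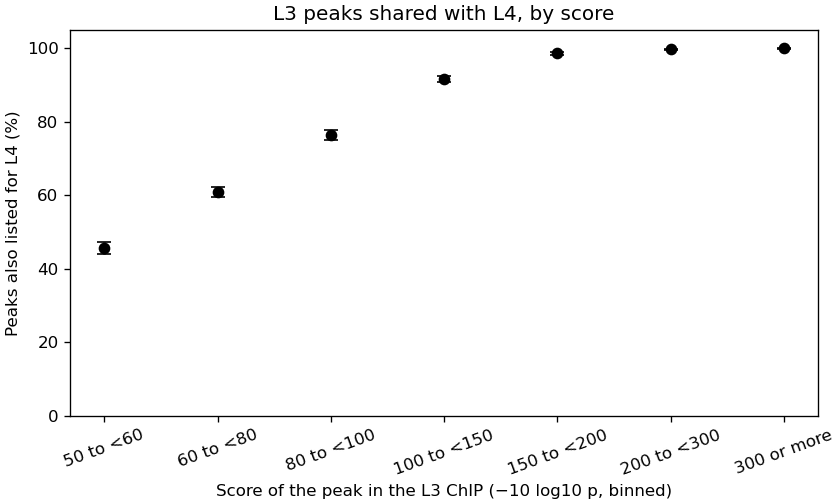
Share of L3 peaks that were also listed for L4 (vertical axis, percent, with exact 95% confidence intervals) by score of the peak in the L3 ChIP (horizontal axis, binned). The share rises from 45.6% in the lowest bin to 100% of 3772 peaks at scores of 300 or more.

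Few single-stage peaks were strong, 42 of L3 alone and 55 of L4 alone with scores of at least 150. The top 10 genes of L3 alone were idhg-1, acr-10, W09H1.3, wbp-2, Y39B6A.21, snt-3, Y23H5B.3, H28G03.5, egl-4 and fbxb-112. The first, idhg-1, an isocitrate dehydrogenase subunit gene, had a peak at chromosome III 4565662 to 4565884, 1630 bp upstream of its TSS, with a score of 258.7 and a fold of 12.3. The peak of egl-4, a cGMP-dependent protein kinase gene, lay in intron 3 of 10 (chromosome IV 1863343 to 1863522, fold 11.2). The insulin receptor gene daf-2 also had an L3 peak, in intron 8 of 16, with a score of 172.95 and a fold of 3.72, and was named after its values were seen.

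The L4 table was led by jun-1, which encodes a Jun-type bZIP transcription factor. Of its L4 peaks, 6 had folds of 47.2 to 50.2 and scores of 852.9 to 3098, whereas the highest fold at any other gene of that table was 20.97. Sites also listed for L3 have no L4 fold, so jun-1 cannot be ranked among all L4 sites. The 6 peaks lay on chromosome II between 9113145 and 9123318. Exons 3, 4, 5 and 6 of 8 each held 1 of them, and 2 were annotated within 1 kb of a TSS. These 2 lay 196 and 331 bp downstream of different start sites. The peak in exon 5 (9122158 to 9122490) held 309 tags. Shared regions at jun-1 included 9112941 to 9113099, with a fold of 27.5 in the L3 ChIP. After jun-1 the L4 table listed W04C9.4, R05G9.1, Y71G12B.33, slc-17.6, R06A10.3, K08H2.2, str-221, col-155 and Y47D7A.15. The peak assigned to W04C9.4 lay in exon 12 of 14 of tol-1, the Toll receptor gene, with a score of 540.9 and a fold of 11.2. That of col-155, a cuticle collagen gene, was annotated 934 bp downstream of a TSS with a fold of 6.96.

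**Figure D2:**
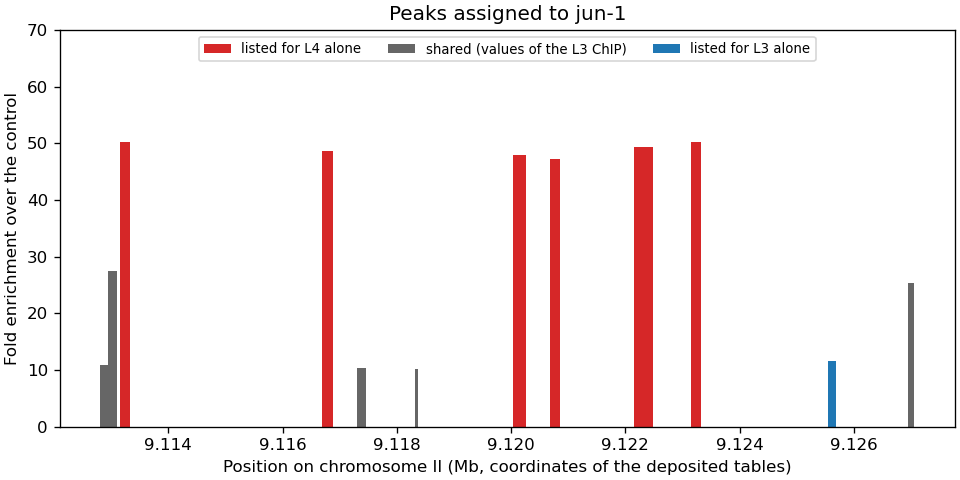
Peaks assigned to jun-1 on chromosome II (horizontal axis, Mb, in the files' coordinates) with their fold enrichment over the control (vertical axis) for peaks of L4 alone, shared regions (L3 values) and peaks of L3 alone. The 6 strong L4 peaks reach folds of 47.2 to 50.2, and the strongest shared region has a fold of 27.5 in the L3 ChIP.

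The combined table gave the strongest shared regions. The highest scores printed were those of Y32H12A.9, gst-11, Y119C1B.3 and Y51B11A.1, the 4 with scores above 3100. A score of exactly 3100, which 61 shared peaks had, was read as a cap, so these peaks cannot be ranked against those 4 or one another by score. The first of them by fold were nlp-81, zig-13, irld-67, tbc-17, Y53G8AM.2 and ddl-2. The region of the neuropeptide gene nlp-81 lay 649 bp upstream of the TSS (chromosome IV 3176377 to 3176936, 465 tags, fold 36.1). At gst-11, a glutathione S-transferase gene, the region was 2401 bp downstream of the TSS (chromosome X 3631334 to 3631951) with a score of 3191 and a fold of 18.2. Of the 21368 shared called peaks, 39 were at least 2 kb long and held 9.58% of all tags in shared peaks. These included the ribosomal RNA repeat at rrn-3.56 (chromosome I 15060207 to 15071396, 14046 tags, fold 15.6), the spliced leader repeat at sls-1.5 (chromosome V 17119773 to 17126662, 7479 tags, fold 15.6) and rrn-4.12 (fold 16.9). The collagen gene rol-6, a common marker for making transgenic worms, lay in the same class, with 6053 tags over chromosome II 8731252 to 8735369 and a fold of 15.5. Folds of all 39 ranged from 4 to 24.4 with a median of 11.9.

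The tagged gene nhr-6 (C48D5.1, chromosome III) had 4 shared regions and 2 peaks of L4 alone. The strongest was intergenic, 6726 bp upstream of the TSS at 3566839 to 3567060, with 90 tags, a score of 618.5 and a fold of 33.96. A weaker region lay 137 bp upstream of the TSS (3573254 to 3573617, fold 10.8). Exons 7 and 9 of 12 fell in 1 shared interval of 3576528 to 3577987 with folds of 3.97 and 4.85, and the L4 peaks were at 3575824 to 3576115 (fold 4.07) and 3576335 to 3576523 (fold 5.81). Of the 10 transgene markers, including rol-6 and nhr-6, 7 had a region at both stages (70%, percentile 85.8 of matched random lists). The others of these were pha-1 (fold 34.3), unc-119 (fold 38.1), ttx-3 (fold 17.3), unc-54 (fold 16.6) and lin-15A (fold 9.81). A peak was listed for L3 alone at dpy-20 and for L4 alone at lin-15B, and none was assigned to myo-2.

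The next comparison asked which genes carried regions at both stages. Of 19971 protein-coding genes in the reference, 9182 (45.98%) were assigned a region at either stage, 7480 at both, 969 at L3 alone and 733 at L4 alone. Counting every type of gene, 9652 genes had a region at both stages, and 178 of them had separate L3 and L4 peaks but no shared region. Genes with a peak of L3 alone often had a separate peak of L4 alone. There were 972 such protein-coding genes, where independent lists of 3219 and 2779 genes would share 447.9, a ratio of 2.17. Long genes collect more peaks, and this ratio is not corrected for length.

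Transfer RNA genes stood apart from other gene types, a comparison chosen after the data were seen. A shared region lay directly over the TSS of 431 of 612 tRNA genes (70.4%, 95% CI 66.6 to 74.0), of 45 of 129 genes for small nuclear RNAs (34.9%, 26.7 to 43.8), of 6 of 346 snoRNA genes (1.73%, 0.639 to 3.74) and of 26 of 15363 piRNA genes (0.169%, 0.111 to 0.248). Protein-coding genes had one in 381 of 19971 cases (1.91%, 1.72 to 2.11). Annotated tRNA pseudogenes had one in 24 of 209 cases (11.5%, 7.50 to 16.6). The gap to tRNA genes was smaller by wider measures, with a shared region within 1 kb of the TSS at 51.2% of pseudogenes and 75.5% of tRNA genes, and any assigned shared region at 62.7% and 78.9%. For protein-coding genes these wider measures gave 20.7% and 36.8%, so their gap to tRNA genes was smaller too. Regions over tRNA genes had a median length of 160 bp and a median fold of 15.3, and examples were W09D6.t1 on chromosome III (11066660 to 11067048, fold 24.5) and C25F6.t1 on chromosome X (5485048 to 5485225, fold 30.99). Each peak was assigned to 1 gene in the files, so a region shared by neighbouring genes counted once.

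**Figure D3:**
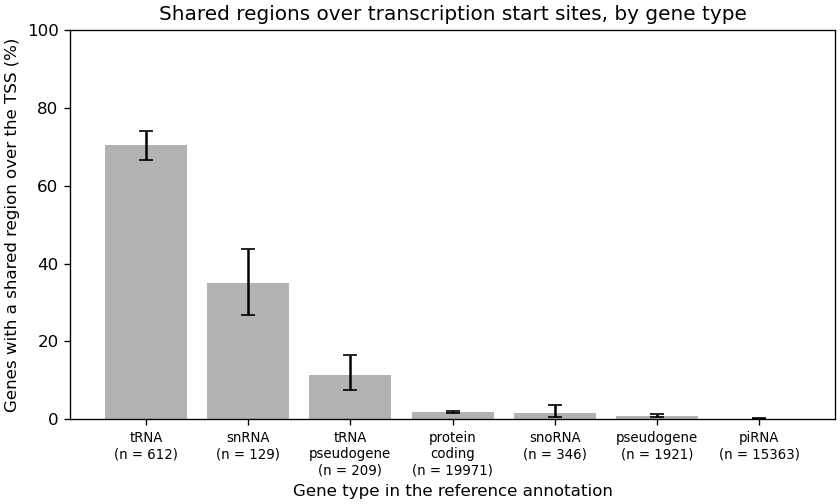
Percent of the genes of each type in the reference annotation (horizontal axis) with a shared region over the TSS (vertical axis), with exact 95% confidence intervals. The tRNA genes reach 70.4%, the snRNA genes 34.9% and protein-coding genes 1.91%.

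Of the 22 gene lists, 5 lay above the random lists in the share of members with regions at both stages, and none lay below. Chance alone would put some of 22 lists outside the limits, and members that lie near each other are not independent. Among the genes of the spermatheca and its contractility, 24 of 29 had regions at both stages, against 18.7 in matched random lists (percentile 98.6). Counted on a shared region they were 23 of 29 at percentile 96.97, within the range. At nmy-1, which encodes a nonmuscle myosin heavy chain, a region 2132 bp upstream of the TSS (chromosome X 2907412 to 2907596) stood at the ceiling with a fold of 49.1. The phospholipase C gene plc-1 had a fold of 33.9. The next was nhr-6 itself, the gene of the GFP fusion, whose signal may reflect transgene copies, and the list was not counted without it. Body wall muscle genes had regions at both stages in 19 of 25 cases (random mean 13.8, percentile 98.8), among them unc-87 (fold 14.1), whose region was among the 39 of at least 2 kb and lay 6167 bp upstream of the TSS, the dystrophin gene dys-1 (fold 20.8), the tropomyosin gene lev-11 (fold 38.1) and the titin-like gene ttn-1 (fold 5.10). Among all L3 regions the muscle list stood at percentile 95.3 and among all L4 regions at 99.7. The spermatheca and muscle lists had 2 members in common, lev-11 and unc-54. In all, 16 members of the spermatheca list also belonged to another list, so its result is not separate from theirs.

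Collagen genes of the col family were frequent among the genes with regions. In the col family 89 of 156 genes had regions at both stages (random mean 45.0), above all 10000 random lists, with 20 further members listed for L4 alone and 5 for L3 alone. The members with the best shared scores were col-52 (fold 11.7), col-175 (fold 33.96), col-99 (fold 31.7) and col-139 (fold 45.9), and they do not stand for the whole family. At the other end, col-133 had a best shared score of 50.56 and a fold of 5.16, 613 bp downstream of the TSS. The best regions of col-52, col-175 and col-99 lay upstream of the TSS and that of col-139 downstream. In most members of the family with a shared region, the best one lay downstream of the TSS. The best peaks of the 20 members listed for L4 alone all lay downstream. The count for this family is therefore not a count of upstream regions, and the cause of this placement was not tested. The list of hypodermis and cuticle genes had 15 of 25 (random mean 9.62, percentile 98.95), led by rol-6, whose region was among the 39 of at least 2 kb, and followed by wrt-2 (fold 39.2), dpy-3 (fold 27.5) and the GATA factor gene elt-1 (fold 26.7). Of its members, 5 also belong to the col family, and counted on a shared region it had 14 of 25 at percentile 97.35, within the range, as it was among all L4 regions (97.1). In the better-scoring 50% of each table, the col family fell to percentile 95.5 and the hypodermis list to 63.5. Homeobox genes of the ceh family had 37 of 64 (random mean 28.9, percentile 98.5), including ceh-99 (fold 8.77), ceh-51 (fold 7.70), ceh-76 (fold 8.29) and ceh-30 (fold 37.4). With peaks within 1 kb of a TSS alone the ceh family stood at percentile 46.1, and among all L3 regions at 94.05.

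**Figure D4:**
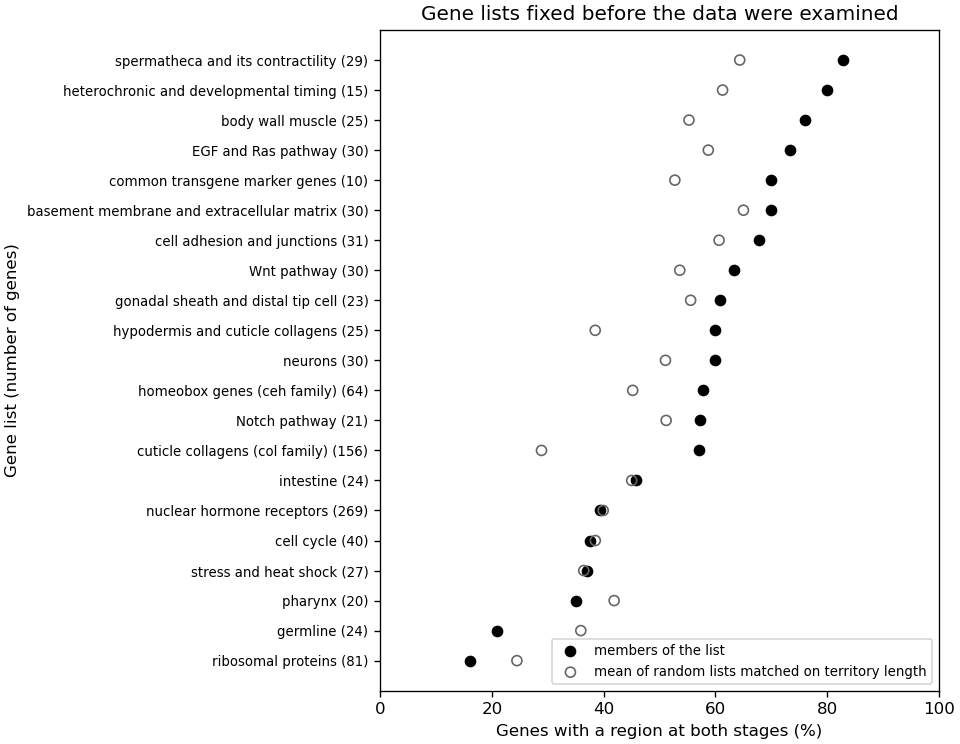
Percent of the genes of each reported list with a region at both stages (horizontal axis) for the list's members (filled points) and the mean of 10000 random lists matched on territory length (open points). Number of genes in brackets. The spermatheca list is highest at 82.8% and the ribosomal protein genes lowest at 16.05%.

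The signalling and adhesion lists lay within the range of the random lists in the main count. EGF and Ras pathway genes had 22 of 30 (percentile 95.6), with lin-2 (fold 31.8), ksr-2 (fold 32.1), lip-1 (fold 43.4) and the EGF receptor gene let-23 (fold 9.24). Heterochronic genes had 12 of 15 (percentile 94.0), with alg-2 (fold 26.3), lin-42 (fold 18.2), lin-14 (fold 37.7) and alg-1 (fold 36.1). Wnt pathway genes had 19 of 30 (percentile 86.4), with elt-6 (fold 40.4), egl-18 (fold 36.7), lin-18 (fold 42.4) and lit-1 (fold 35.7). Notch pathway genes had 12 of 21 (percentile 71.2), with apx-1 (fold 19.4), sel-8 (fold 29.0), lag-2 (fold 33.8) and lst-1 (fold 37.6). Cell adhesion and junction genes had 21 of 31 (percentile 80.1), but lay above the random lists with peaks within 1 kb of a TSS (percentile 99.2), in the better-scoring 50% of each table (98.95) and among all L4 regions (99.4). Among all L3 regions the percentile was 75.1. They were led by the afadin gene afd-1, which had 49 shared regions, followed by cdh-4 (fold 28.6), par-3 (fold 39.0) and vab-10 (fold 33.5). Basement membrane genes had 21 of 30 (percentile 71.6), with mig-6 (fold 40.1), adt-2 (fold 35.4), ptp-3 (fold 27.3) and cle-1 (fold 23.7).

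Lists for other tissues and processes also lay within the range. Gonadal sheath and distal tip cell genes had 14 of 23 (percentile 70.7), with gsa-1 (fold 30.7), apx-1, vab-1 (fold 45.3) and mig-6. Neuronal genes had 18 of 30 (percentile 84.6), with unc-64 (fold 33.9), unc-119, snb-1 (fold 30.4) and unc-10 (fold 27.8). Intestinal genes had 11 of 24 (percentile 53.6), with act-5 (fold 41.3), ges-1 (fold 39.1), pgp-1 (fold 38.3) and fat-6 (fold 28.2). Pharyngeal genes had 7 of 20 (percentile 25.8), with tbx-2 (fold 44.5), pha-4 (fold 41.3), peb-1 (fold 42.6) and eat-2 (fold 19.7). Stress and heat shock genes had 10 of 27 (percentile 53.4), with daf-16 (fold 29.9), skn-1 (fold 46.2), egl-9 (fold 42.6) and sod-1 (fold 31.8). Cell cycle genes had 15 of 40 (percentile 45.1), with efl-2 (fold 21.3), cyd-1 (fold 33.2), lin-23 (fold 34.2) and efl-1 (fold 19.01). Nuclear hormone receptor genes had 106 of 269 (percentile 42.9), with nhr-87 (fold 29.98), nhr-88 (fold 23.9), nhr-70 (fold 12.7) and nhr-10 (fold 35.3). The lowest percentiles were those of germline genes, with 5 of 24 (percentile 5.14), among them mex-3 (fold 35.96), syp-3 (fold 10.1), glh-2 (fold 3.21) and daz-1 (fold 9.38), and of ribosomal protein genes, with 13 of 81 (percentile 3.04), among them rps-27A (fold 24.3), rps-28 (fold 22.1), rpl-11.1 (fold 31.1) and rpl-38 (fold 25.7). Counted on a shared region, the germline genes had 4 of 24 at percentile 2.17, below the random lists, and among all L3 regions the ribosomal protein genes stood at 0.965.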

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

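The alternatives named as later additions below were chosen after the data were seen. Removal of the widest 1% of peaks left 80.6% of L3 regions and 82.2% of L4 regions in common, for which no interval was computed. The better-scoring 50% of each table left the shares within 1 kb of a TSS inside their 95% intervals. A promoter window of 3 kb raised the share near a TSS to 73.3% for L3 alone, 72.0% for L4 alone and 70.9% for shared entries, by its own construction. As later additions, the L3 and L4 regions in common were 77.3% and 78.9% where 1 called peak had to fill at least 50% of the shared interval, and 81.4% and 83.0% with shared entries not merged. A score of at least 100, also a later addition, gave 96.8% for L3, and no such value exists for L4 because the shared table holds no L4 scores. Genes with a region at both stages numbered 5835 with peaks within 1 kb of a TSS and 6125 in the better-scoring 50%, by construction with fewer peaks, and 8821 within 3 kb. With random lists not matched on length, 14 gene lists lay above the limits in place of 5, and 1 lay below (ribosomal proteins) in place of 0. The ceh family moved to percentile 46.1 with peaks within 1 kb of a TSS, and the cause was not tested. The spermatheca list stood at 99.4 within 1 kb and 98.8 in the better-scoring 50%, and body wall muscle at 99.9 and 99.96. Cell adhesion and junction genes rose to percentile 99.2 and 98.95 in the same settings. Without rol-6, whose signal may reflect transgene copies, the hypodermis list stood at 98.3 (14 of 24), a later addition, and whether the transgenes carry rol-6 is not given in the sources used here. The ratio of shared to L3 strength was 1.43 by fold and, as later additions, 1.89 by tags and 2.05 by score where 1 called peak filled at least 50% of the interval. Overlap of 50% between the peaks themselves, distance between centres and equal numbers of top-ranked peaks were not run because the shared table gives 1 interval for both stages, and the mitochondrial chromosome held no peaks to remove. The 2 NR4A motif alternatives and its window were not run, since no genome sequence was used here. No paired analysis was possible because each stage had 1 ChIP library. Library depth is unknown, which leaves open how many single-stage peaks lay just under the threshold of the other library.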

Other observations

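All tests in this part were chosen after the results were seen. The single-stage peaks over tRNA genes were uneven between the stages. Of the peaks of L4 alone, 55 lay over the TSS of a tRNA gene, out of 148 over any TSS, and of the peaks of L3 alone 2 did, out of 68. The L4 peaks had a median fold of 8.20 in their own library, and 44 tRNA genes had a peak of L4 alone and no shared region, compared with 8 for L3 alone. At any distance from the TSS the difference was smaller. There, 129 peaks of L4 alone (2.84%) and 82 peaks of L3 alone (1.62%) were assigned to tRNA genes. These numbers rest on 1 ChIP library per stage.

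For the tRNA genes with a shared region over the TSS, recovery of strongly transcribed genes in general may contribute and stays open. Ribosomal protein genes had such a region in 0 of 81 cases (0%, up to 4.45%), whereas 34.9% of snRNA genes had one, so that the gene classes do not decide it. Reads shared between near-identical tRNA copies also stay open. The annotated tRNA pseudogenes had a region over the TSS in 11.5% of cases and within 1 kb of it in 51.2%, but pseudogenes hold diverged sequence and no sequence was analysed here. No precipitation from animals without the tag was analysed here, and no biological explanation was tested.

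A candidate explanation for the jun-1 peaks of L4 alone is spliced jun-1 DNA, such as a cDNA or plasmid, in the L4 ChIP library. It stays open, because the place of 4 of the 6 peaks in exons prompted it and cannot test it, and the promoter class of the other 2 does not tell exon from intron. Extra genomic copies of the whole locus, as a source of continuous signal, are argued against by the peaks of L4 alone, which covered 12.6% of the 10174 bp they span. That figure leaves out L4 signal at sites also listed for L3, so it is a limited test. The near-equal folds, at 63 to 67 steps, say little if the L4 folds have a ceiling near the 68 steps of the shared peaks. Such a ceiling was not shown for L4, because its maximum of 67 steps was set by these peaks themselves. Binding at the L4 stage stays open because stage, strain and library coincide. No other gene in the L4 table exceeded a fold of 20.97. That cannot weigh on L4 binding, because sites also listed for L3 are absent from it and carry L3 values.

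Peaks of L3 alone may largely be weak peaks near the calling threshold that were missed in the L4 library. All L3 peaks scoring at least 300 (100%) were shared, and the shared part fell step by step with lower scores. The same share cannot be computed for L4. A place near the threshold does not describe the 10 peaks of L4 alone that scored at least 300, but this follows from their selection by score and is no separate test. Of these, 6 lay at jun-1 and 4 at W04C9.4 (score 540.9), R05G9.1 (455.5), Y71G12B.33 (363.8) and slc-17.6 (358.1). A difference between stages or strains stays open for the 42 peaks of L3 alone and 55 peaks of L4 alone that scored at least 150, and cannot be told apart from a difference between libraries with 1 ChIP each.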
